A study of Homo sapiens with 220 samples.

How the data were processed

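RNA was measured with GeoMx Digital Spatial Profiling, an assay in which gene probes carrying a sequence tag are hybridised to a tissue section, released by light from a region chosen under the microscope, and counted by sequencing. The series held 220 regions of 16 human lungs: 150 vessel regions from 11 lungs with idiopathic pulmonary arterial hypertension (IPAH) and 67 from 5 control lungs entered the comparisons, and 3 regions whose labels name only "Lymph" entered none. Regions were chosen mainly by histology, per the series design text, and 7 of them were captured as a segment by smooth muscle actin staining, per the labels. All 7 came from a single IPAH donor, and no control region was segmented. In that donor intima and media were captured as actin-positive and adventitia as actin-negative segments. Genes of the smooth muscle contractile list, ACTA2 among them, therefore bear on how some regions were picked. The design text states 211 regions and the files hold 220; apart from the 3 lymph regions, the 6 further ones lie in IPAH intima and media (1), control intima and media (2) and control adventitia (3), and all were kept.

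The count table was used as deposited: whole-number counts per probe for 18815 probes known by a code, made with the GeoMx NGS pipeline, version 2.0.0 for plates 1 to 3 and 2.3.4 for plate 4, per the file headers. The other values read were the raw and aligned read totals, which stand beside the same counts in each region's deposited file, per the file headers. The counts in the 220 region files were identical to those in the table. Aligner, probe annotation and genome build are not given in the sources used here. A second table held the authors' normalized log2 values for 8272 genes with gene symbols. How the authors normalized them and chose the genes is not stated, so centring and scale factors stay unknown; column medians ran from -0.32 to -0.08 and values from -10.75 to 9.63.

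The count table carries no gene symbols. After 5 factors shared by all genes were removed, each of the 8272 rows of log2 values matched exactly 1 probe's log2(count + 1) (largest residual 5e-07 on the log2 scale, next-best correlation at most 0.986), which named 8272 probes. The remaining 10543 probes stayed unnamed and no probe is marked as a negative control. The factors explained 0.997 of the variance of the log2 total count and 0.913 of that of membership in plate 4, against 0.275, 0.209 and 0.15 for plates 1, 2 and 3 and 0.228 for IPAH against control. The authors' log2 values therefore had depth and most of the plate 4 difference removed. Of the 8272 symbols, 8188 were in the RefSeq gene table of GRCh38.p14, used for names only. After 6 Y-linked or X-inactivation genes were left out, 8266 genes were analysed. The named probes held a median of 56.2% of a region's counts. Across regions the median named gene lay at 1.25 times the median unnamed probe, 1323 genes lay above 1.5 times and 505 above 2 times. Whether the unnamed probes stand for background is not stated. If they do, fold changes of genes near their level would be compressed.

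Total probe counts per region ran from 106520 to 15669811 with a median of 458133. The counts behave as a sampled set of molecules, and intervals from counting cover counting error only. Over 428 pairs of regions of the same donor and type, the lowest chi-square per degree of freedom was 1.06 and the median 2.09. Sampling noise alone gives a value near 1, which the median exceeds. No p was computed for the lowest, so it cannot tell whether that pair differs beyond sampling noise.

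The replicate was the donor, given in the labels; the same label pairs region types of 1 donor. Counts of a donor's regions of 1 type (2 to 12 regions) were summed into 1 library. Plates are given in the labels: plate 1 held 6 IPAH donors, plate 2 held 3 IPAH and 5 control donors, plate 3 held 2 control donors, and plate 4 held 3 IPAH donors and 1 control donor, with 4 of the 16 donors on 2 plates. Each of the 10 comparisons used edgeR 4.0.16 quasi-likelihood tests (glmQLFit, glmQLFTest) in R 4.3.3 with TMM factors, filterByExpr (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment over 8266 genes, called at an adjusted p under 0.05. IPAH was compared with control using the share of a donor's regions on plates 1, 3 and 4 as covariates, and region types within a lung with the donor as a block. The difference of the disease effect between adventitia and intima and media was tested as an interaction with the donor as a block. Fold changes are on the log2 scale with the standard error (SE) of the fit; group levels are CPM, the usual depth-scaled counts of edgeR, over named genes after TMM scaling.

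Gene lists were 33 sets of known markers and pathways fixed before the data were examined: smooth muscle contractile, pericyte, general, arterial, capillary, venous and systemic, and lymphatic endothelial, adventitial fibroblast, fibrillar collagen and matricellular, basement membrane, elastic fibre, proteoglycan and cartilage-type matrix, TGF-beta responsive, BMP pathway, pulmonary hypertension risk genes, vasoactive signalling, hypoxia and glycolysis, angiogenic sprouting, mesenchymal transition factors, proliferation, interferon response, complement, macrophage, T and NK cell, B and plasma cell, mast cell, neutrophil, alveolar and airway epithelial, red blood cell, Schwann cell and nerve, coagulation and fibrinolysis, and cytosolic ribosomal proteins. The 32 with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 32, and again with an estimated correlation. Camera compares a list with the other genes. A donor-level test was added after the data were seen: the mean log2 CPM of a list (prior count 2) per donor, with an exact permutation of 16 donors (4368 assignments) or exact sign flips of 11 donors (2048) or 5 donors (32), two-sided. The permutation has no plate term, so against control it does not set plate apart from disease.

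Genes are named by a rule fixed before the data were examined: among called genes at or above the median level and moving one way in at least 80% of donors (or, against control, in the fits without plate covariates and within plate 2), the 10 largest rises and 10 largest falls; from each list up to 4 called members per direction with the smallest p; and the 3 genes with the smallest p where nothing was called. Genes outside it are said to be so. Immunoglobulin heavy chain and HLA genes have near-identical copies, and their probes cannot be assumed to separate them.

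The code was tested on counts simulated from the real means and library sizes with 200 genes changed. Of genes changed by log2 0.5, the share recovered was 64.2% for IPAH against control intima and media, 37.3% for obliterative and 46.3% for plexiform lesions against control, 49.3% for the adventitia comparison, and 59.7% for the interaction; it was 100% for obliterative and for plexiform lesions against IPAH intima and media, 98.5% for plexiform against obliterative lesions and for IPAH adventitia against intima and media, and 88.1% for the control adventitia comparison. Genes in these simulations vary independently, which real genes do not. Alternatives were DESeq2 1.42.0, upper-quartile factors, no low-count filter, region means with limma-trend, other plate and donor terms, single plates, each control donor left out, and regions without the segmented ones; added after the data were seen were all probes in the scaling, the authors' log2 values with limma, a filter at 2 times the median unnamed probe, regions without those over 10 times the median total, and the donor-level list test. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.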

Results

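Gene expression was measured in regions of pulmonary vessels selected under the microscope in sections of human lung. The comparisons used 36 regions of intima and media and 31 of adventitia from 5 control donors. They also used 37 regions of intima and media, 37 of adventitia, 37 of obliterative lesions and 39 of plexiform lesions from 11 donors with idiopathic pulmonary arterial hypertension (IPAH), a disease in which the lung arteries narrow. Obliterative lesions are vessels whose lumen is filled by an expanded intima, and plexiform lesions are tangles of small channels beside an artery. The median total probe count per region was 366051 in control intima and media, 399265 in control adventitia and 675865 in IPAH intima and media. It was 569468 in IPAH adventitia, 410252 in obliterative lesions and 1023421 in plexiform lesions. Plates differed in depth as well, with medians of 947366 on plate 1, 434526 on plate 2, 397080 on plate 3 and 230735 on plate 4. Plate 1 held IPAH donors only and plate 3 control donors only, so IPAH and control met on plates 2 and 4. Levels are CPM (depth-scaled counts of named genes) as mean ± SD over donors. Changes are log2 fold changes ± SE from edgeR, with n = 16 donors against control, 11 IPAH donors within the disease and 5 donors within the controls. Adjusted p of lists come from camera at the preset correlation unless an estimated correlation is named.

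**Figure D1:**
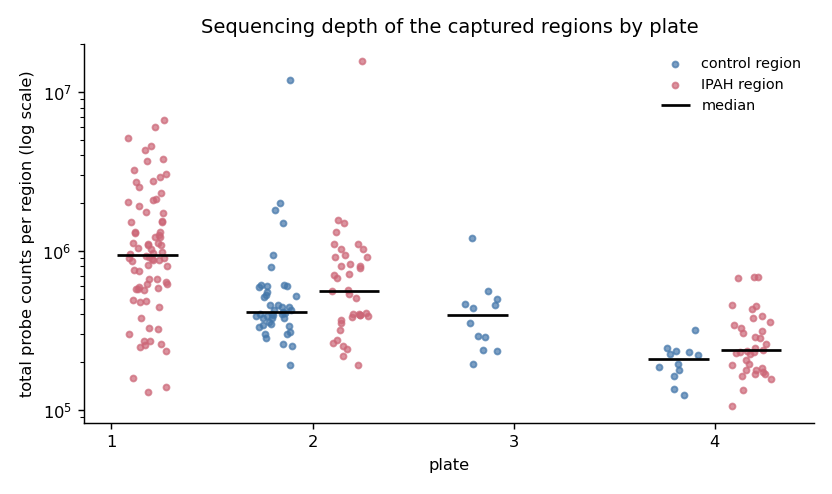
Total probe counts per region (log axis) by plate, with IPAH and control regions marked and bars at the median of each plate and state. Over all regions of a plate the median was 947366 on plate 1, which held IPAH regions only, and 230735 on plate 4.

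**Figure D2:**
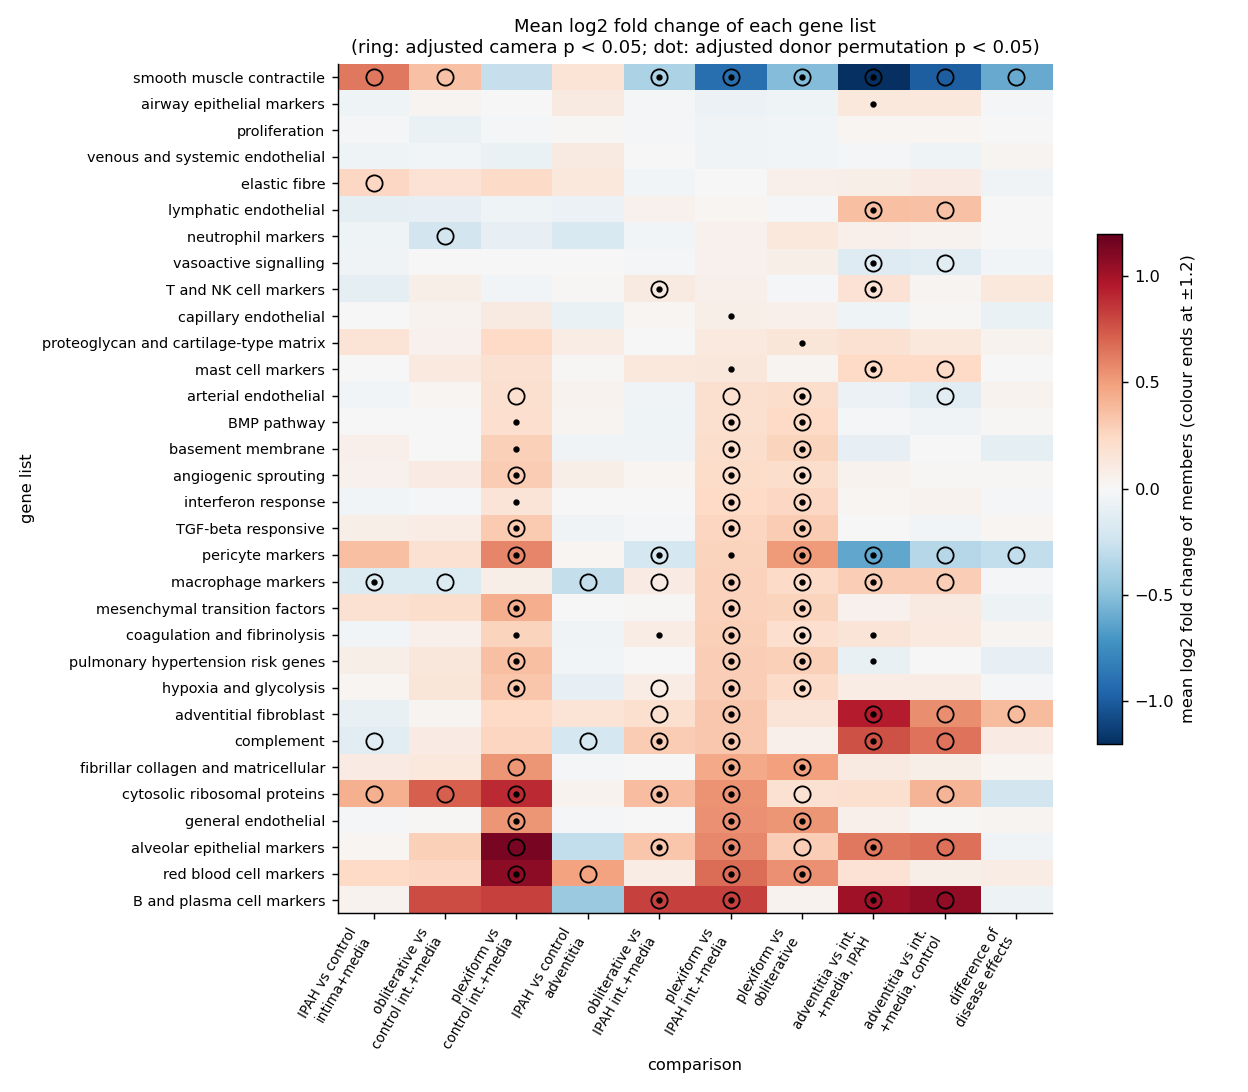
Mean log2 fold change of each gene list (rows) in each of the 10 comparisons (columns). Rings mark lists with an adjusted camera p under 0.05 at the preset correlation and dots those under 0.05 in the donor-level permutation test, a test chosen after the data were seen. The smooth muscle contractile list was lowest in adventitia, at -1.58 against intima and media in IPAH.

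IPAH adventitia was compared with intima and media of the same 11 lungs to describe how the layers of the diseased vessel wall differ. All 15 measured genes of the smooth muscle contractile list fell in adventitia (15 when adjusted over the list alone). MYH11, the smooth muscle myosin heavy chain, stood at 186 ± 94 CPM against 1323 ± 608 (log2 -2.79 ± 0.24, adjusted p = 8.24e-09, lower in 11 of 11 donors). ACTA2, the smooth muscle actin, was 5.96-fold lower (-2.58 ± 0.27) and TAGLN, an actin-binding protein of smooth muscle, changed by -2.36 ± 0.26. In 1 of the 11 donors the layers were segmented by smooth muscle actin, adventitia as negative and intima and media as positive. Its fall in these genes follows from capture. Without the segmented regions 90 of the 100 genes named for this comparison kept their call and 10 lost it. Of 13 adventitial fibroblast genes 11 rose (13 adjusted over the list alone). DCN, a small matrix proteoglycan, stood at 506 ± 251 against 130.03 ± 45.3 CPM (1.81 ± 0.20, higher in 11 of 11 donors). SFRP2, a secreted Wnt modulator, rose by 1.78 ± 0.23 and CCDC80, an extracellular matrix protein, by 1.06 ± 0.12. Immunoglobulin transcripts of plasma cells rose most: IGKC, the kappa light chain, stood at 5096 ± 5043 against 547 ± 974 CPM (3.18 ± 0.40, higher in 11 of 11 donors), and IGHA1 rose by 2.16 ± 0.37.

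In the same comparison 437 of 8266 genes rose and 377 fell. Of 12 B and plasma cell genes 9 rose (10 adjusted over the list alone). Of 14 complement genes 10 rose (12 over the list alone), with C3, the central complement component, at 1.72 ± 0.19, C7 at 1.71 ± 0.22 and CFD, a protease of the alternative pathway, at 1.67 ± 0.18. Among the 15 macrophage genes 9 rose, including LYZ, lysozyme (0.74 ± 0.13). CD74, the class II invariant chain, rose by 1.92 ± 0.25. Some genes of other cell types rose too: 3 of 5 lymphatic endothelial genes, with CCL21, a chemokine of lymphatic vessels, at 1.14 ± 0.17, and 3 of 9 T and NK cell genes (6 over the list alone). So did 2 of 6 mast cell genes, with the tryptase TPSAB1 at 0.95 ± 0.17, and 9 of 12 alveolar epithelial genes, with SFTPB, a surfactant protein, at 1.43 ± 0.25. Pericyte markers fell in 4 of 5 (5 over the list alone), with RGS5, a regulator of G-protein signalling, at -1.16 ± 0.14 and NOTCH3 at -0.85 ± 0.10. In the vasoactive signalling list 4 of 15 genes fell (6 over the list alone), including the phosphodiesterase PDE3A (-0.43 ± 0.07) and the cGMP-dependent kinase PRKG1 (-0.30 ± 0.07). PMP22, the one measured Schwann cell gene, rose by 0.32 ± 0.07 and its list was not tested. By camera 11 of 32 lists were called. The calls for smooth muscle (adjusted p = 1.35e-72), adventitial fibroblast (3.15e-28), complement (2.47e-19), B and plasma cell (2.68e-13) and pericyte (1.9e-11) held with an estimated correlation, at adjusted p = 0.00182, 0.0112, 0.0204, 0.043 and 0.0112. The other 6, at adjusted p from 3.81e-09 to 0.0397, were lost, at adjusted p = 0.126 with an estimated correlation for alveolar epithelial, 0.116 for macrophage and 0.0921 for vasoactive signalling genes. It was 0.0921 for lymphatic endothelial, 0.186 for T and NK cell and 0.4 for mast cell genes. In the authors' log2 values 332 genes were called in place of 814, and with the background filter 190, 84 higher and 106 lower. When all probes set the scaling 371 were higher and 241 lower.

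In the 5 control lungs the layers were compared in the same way. In adventitia 4 of 12 B and plasma cell, 7 of 14 complement and 6 of 13 adventitial fibroblast genes rose, and these lists' calls were lost (adjusted p = 0.0685, 0.0926 and 0.0685 with an estimated correlation). IGKC stood at 2007 ± 1639.9 against 113 ± 41.3 CPM in intima and media (log2 3.70 ± 0.64, higher in 5 of 5 donors). IGHA1 rose by 3.28 ± 0.62, and C3 (1.41 ± 0.23), CFD (1.42 ± 0.24) and DCN (1.36 ± 0.28) rose. The scavenger receptor CD163 rose by 0.85 ± 0.17 and CD68, another macrophage gene, by 0.73 ± 0.10. ACTA2 fell by 1.88 ± 0.47 on the log2 scale and MYH11 changed by -1.78 ± 0.39, from 524 ± 322 CPM in intima and media to 129 ± 19.7. The test called 55 genes higher and 31 lower. By list, 6 of 15 smooth muscle genes fell (15 adjusted over the list alone), 7 of 14 complement genes rose (10) and 6 of 13 adventitial fibroblast genes (10), where the number in parentheses is that adjusted over the list alone. Likewise 6 of 15 macrophage genes rose (8, with 1 lower), 4 of 12 B and plasma cell genes (5), and 1 each of 5 lymphatic endothelial (3), 6 mast cell (2) and 12 alveolar epithelial genes (7). In the pericyte list 1 of 5 genes fell (2 over the list alone), and 1 of 12 arterial endothelial genes (2). No ribosomal protein or vasoactive signalling gene passed, although camera called these lists higher and lower, at means of 0.41 and -0.13.

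Camera called 12 lists in the control lungs, at adjusted p = 5.25e-34 for smooth muscle, 6.41e-23 for complement and 1.05e-19 for adventitial fibroblast genes. None was kept with an estimated correlation, where the smallest adjusted p was 0.0685 with an estimated correlation and the largest 0.488. With 5 pairs of libraries an exact permutation of signs cannot give a p under 0.0625. Single donors moved the number of called genes: it was 104, 58, 9, 3 and 196 without control donor 1, 2, 3, 4 and 5, and 33, 26 higher and 7 lower, when all probes set the scaling. With the background filter 35 genes were higher and 50 lower.

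Plexiform lesions were compared with intima and media of the same 11 lungs to describe how this lesion differs from them. Of 15 general endothelial genes 10 rose in the lesions, and the list's call was lost (adjusted p = 0.164 with an estimated correlation). PECAM1, an adhesion molecule of endothelium, stood at 327 ± 143 against 118 ± 27.7 CPM (log2 1.35 ± 0.15, adjusted p = 6.58e-07, higher in 11 of 11 donors). The TGF-beta co-receptor ENG rose by 1.03 ± 0.13, the tight junction gene CLDN5 by 1.01 ± 0.16 and VWF, the von Willebrand factor, by 0.86 ± 0.14. HLA-B, a class I heavy chain of antigen presentation, was 4.45-fold higher (2.16 ± 0.16) and CD74, the class II invariant chain, 4.18-fold (2.07 ± 0.16), each in 11 of 11 donors. All 15 smooth muscle genes fell, with MYH11 at 479 ± 310.0 against 1287 ± 592 CPM (-1.50 ± 0.15) and CNN1, calponin, at -1.37 ± 0.13. In 1 of the 11 donors intima and media were actin-positive segments while plexiform regions were captured whole, which bears on that donor's fall. IGKC rose by 2.71 ± 0.22 and IGHG1, a heavy chain, by 2.23 ± 0.31. Their levels varied between donors, with IGKC at 6095 ± 14439.9 CPM.

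The test called 1356 genes higher and 1325 lower. Camera called 20 of 32 lists, at adjusted p from 1.14e-25 to 0.0285. No list was kept, with adjusted p from 0.0607 to 0.424 with an estimated correlation. Adjusted over the list alone 10 of the general endothelial genes rose, and over all genes 7 of 12 arterial endothelial genes rose while HEY2 fell by 0.25 ± 0.05. Among matrix genes 11 of 18 fibrillar collagen and matricellular genes rose (13 over the list alone), with COL3A1 at 1.14 ± 0.18 and the fibronectin gene FN1 at 1.02 ± 0.17. So did 9 of 15 basement membrane genes, with COL4A1 at 0.80 ± 0.14, while COL4A5 fell by 0.33 ± 0.06. Of 15 TGF-beta responsive genes 7 rose and 3 fell, with TGFB1 at 0.57 ± 0.09. TGFB3, at -0.17 ± 0.05, turned in the authors' log2 values. In the BMP list 6 of 17 rose, with SMAD6, an inhibitory SMAD, at 0.66 ± 0.09 and ID1, a BMP target, at 0.70 ± 0.10. Of 11 pulmonary hypertension risk genes 6 rose and 3 fell. ACVRL1, a BMP9 receptor, rose by 0.63 ± 0.09, AQP1, a water channel, by 0.94 ± 0.12. BMPR2, the BMP type II receptor, outside the rule and chosen after its values were seen, rose by 0.33 ± 0.08. The potassium channel KCNA5 changed by -0.42 ± 0.07 and the transcription factor TBX4 by -0.29 ± 0.07. Hypoxia and glycolysis genes rose in 9 of 13, with ENO1, a glycolytic enzyme, at 0.66 ± 0.09 and VEGFA at 0.46 ± 0.09. Angiogenic sprouting genes rose in 6 of 12 (7 over the list alone), mesenchymal transition genes in 4 of 8, with MMP2, a matrix protease, at 0.68 ± 0.08, and interferon response genes in 3 of 10, with IFI27 at 1.08 ± 0.15.

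Genes of other cells also moved in plexiform lesions. Of the complement list 10 of 14 rose (11 over the list alone) and CLU fell, and 8 of 15 macrophage genes rose and MARCO and FABP4 fell. Further, 7 of 12 B and plasma cell genes rose (8), and 8 of 13 adventitial fibroblast genes rose (8, with 1 lower). All 3 red blood cell genes rose, with HBA2 at 1.00 ± 0.18, and 7 of 12 alveolar epithelial genes (8), with SFTPB at 1.29 ± 0.24 and SFTPC at 1.29 ± 0.28. So did 6 of 14 coagulation genes with 1 lower (7), and 14 of 16 ribosomal protein genes (16), with RPS2 at 0.83 ± 0.12. Outside called lists, the pericyte gene RGS5, outside the rule and chosen after its values were seen, stood at 0.31 ± 0.16 (adjusted p = 0.15) and turned with the background filter. Elastic fibre genes rose in 3 and fell in 3 of the measured 14. Vasoactive signalling genes rose in 2, ECE1 (1.01 ± 0.09), which processes endothelin, and NOS3 (0.55 ± 0.09), the endothelial nitric oxide synthase, and fell in 2, PRKG1 (-0.38 ± 0.06) and PDE5A (-0.22 ± 0.06). Camera gave adjusted p = 1.14e-25 for the smooth muscle list and 3.33e-11 for the general endothelial list, and with an estimated correlation adjusted p = 0.0607 and 0.164. The donor-level permutation test called 22 lists: the smooth muscle mean was lower in 11 of 11 donors (-0.89 ± 0.32, SD) and the general endothelial mean higher in 11 of 11 (0.55 ± 0.34). When all probes set the scaling 2503 genes rose and 212 fell, and in the authors' log2 values 462 genes were called.

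**Figure D3:**
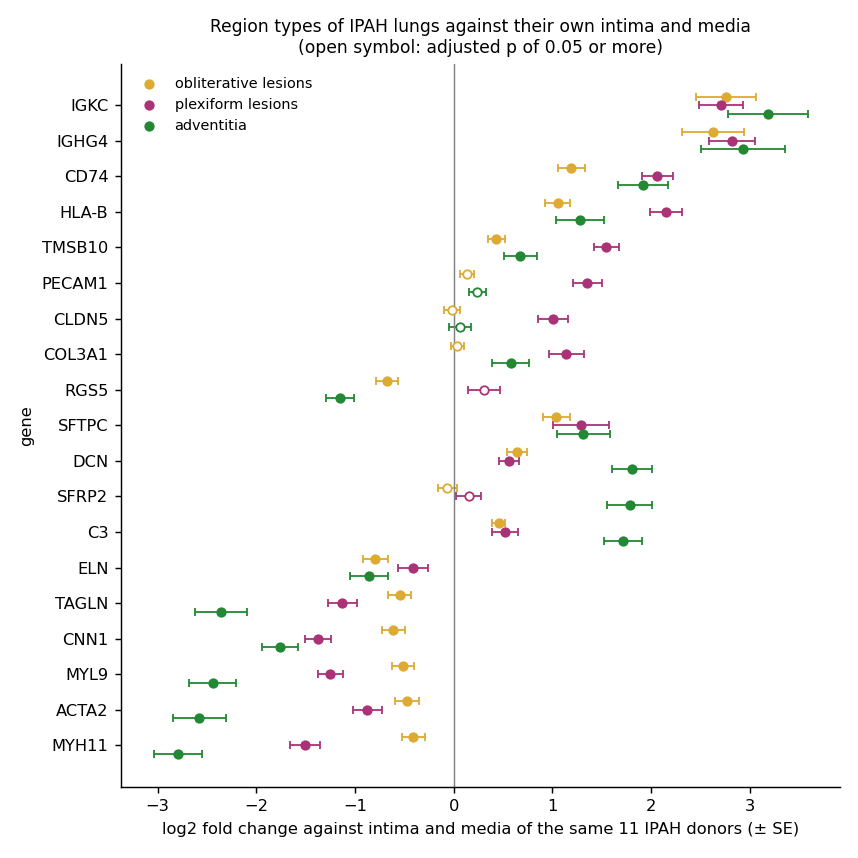
Log2 fold change ± SE of 19 genes in obliterative lesions, plexiform lesions and adventitia against intima and media of the same 11 IPAH donors, with open symbols for adjusted p of 0.05 or more. PECAM1 stands at 1.35 in plexiform lesions, and MYH11 at -1.50 there and -2.79 in adventitia.

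Obliterative lesions were compared with the same intima and media to describe the second lesion type. Plasma cell genes rose most. IGKC stood at 3505 ± 4108 against 551 ± 981 CPM (log2 2.76 ± 0.30, adjusted p = 4.21e-07, higher in 10 of 11 donors). IGHG2 rose by 2.65 ± 0.31 and JCHAIN, which joins IgA and IgM, by 0.93 ± 0.13, and JCHAIN and IGLL5 turned in the authors' log2 values. CD74 was 2.29-fold higher (1.19 ± 0.14, 11 of 11 donors) and HLA-B 2.07-fold (1.05 ± 0.12). Of the smooth muscle list 10 of 15 fell (12 adjusted over the list alone), with CNN1 at -0.61 ± 0.12 and ACTA2 at -0.47 ± 0.12. Elastin, ELN, stood at 301 ± 227 against 533 ± 355 CPM (-0.79 ± 0.13, lower in 11 of 11 donors). Surfactant genes rose, SFTPC by 1.04 ± 0.13 and SFTPB by 0.88 ± 0.12, and both turned in the authors' log2 values.

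The test called 245 genes higher and 92 lower. By list, 7 of 12 B and plasma cell genes rose (9 over the list alone), 9 of 14 complement genes (11), with A2M, a protease inhibitor, at 0.89 ± 0.12 and C7 at 0.82 ± 0.11. So did 6 of 12 alveolar epithelial genes (7), 4 of 13 adventitial fibroblast genes (6, with 1 lower), with DCN at 0.64 ± 0.10, 3 of 15 macrophage genes (7) and 2 of 13 hypoxia and glycolysis genes (4). In the ribosomal protein list 10 of 16 rose (14), with RPS19 at 0.53 ± 0.11, and 2 of 5 pericyte genes fell (3), with RGS5 at -0.68 ± 0.11. No T and NK cell gene passed (2 over the list alone). Camera called these 10 lists, at adjusted p from 2.06e-16 to 0.0462. Those for B and plasma cell (4.07e-16) and complement (1.67e-13) genes were kept with an estimated correlation, at adjusted p = 0.0349 and 0.0466. The call was lost for smooth muscle (adjusted p = 0.0725 with an estimated correlation), ribosomal protein, alveolar, adventitial fibroblast, pericyte and T and NK cell (about 0.132 each), hypoxia (0.209) and macrophage (0.316). The donor-level permutation test called 8 lists: the complement mean was higher in 11 of 11 donors (0.28 ± 0.19, SD) and the smooth muscle mean lower in 10 of 11 (-0.38 ± 0.28). With the authors' log2 values 1 gene was called in place of 337, and with the background filter 80 were higher and 100 lower. When all probes set the scaling 308 were higher and 32 lower.

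Plexiform and obliterative lesions of the same 11 donors were then set against each other. Of the general endothelial genes 12 of 15 rose in plexiform lesions, and of the pericyte markers 3 of 5. PECAM1 stood at 321 ± 141 against 127 ± 30.9 CPM (log2 1.21 ± 0.15, adjusted p = 2.08e-05, higher in 10 of 11 donors). RGS5 stood at 210.4 ± 98.2 against 95.8 ± 50.5 (1.098 ± 0.15, 11 of 11 donors) and COL3A1 rose by 1.17 ± 0.17. MYH11 changed by -1.09 ± 0.17 (lower in 11 of 11 donors) and MFAP4, an elastic fibre protein, by -0.85 ± 0.12. SCGB1A1, a secretory airway protein, changed by -0.81 ± 0.12. The immunoglobulin genes gave no difference past the test, with IGKC at -0.07 ± 0.47 (adjusted p = 0.954) and IGHG1 at 0.22 ± 0.32 (0.706).

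The test called 587 genes higher and 240 lower in plexiform lesions. Camera called 18 lists, at adjusted p from 4.54e-23 to 0.00662. Adjusted over the list alone, 13 general endothelial genes and 4 pericyte markers rose. Basement membrane genes rose in 7 of 15 (8 over the list alone, with 1 lower), with COL4A1 at 0.91 ± 0.16. Pulmonary hypertension risk genes rose in 6 of 11 with 2 lower, with ACVRL1 at 0.68 ± 0.08 and, outside the rule and chosen after its values were seen, BMPR2 at 0.30 ± 0.08. Smooth muscle genes fell in 11 of 15 (13). Those 5 lists were kept with an estimated correlation, at adjusted p = 0.0454, 0.0454, 0.0454, 0.0462 and 0.0462. The other 13 were not. They were fibrillar collagen (12 of 18 rose, adjusted p = 0.108 with an estimated correlation), BMP (6 of 17, 0.0846), with ID1 at 0.81 ± 0.11, TGF-beta responsive (6 of 15 with 1 lower, 0.107), with TGFB1 at 0.56 ± 0.10. Further ones, with p given likewise, were hypoxia and glycolysis (6 of 13, 0.156), arterial endothelial (6 of 12, 0.173), mesenchymal transition (3 of 8, 0.0774), with VIM, vimentin, at 0.69 ± 0.14. The last were angiogenic sprouting (3 of 12, 0.0604), red blood cell (3 of 3, 0.156), interferon response (3 of 10, 0.164), macrophage (6 of 15, 0.382), coagulation (3 of 14, 0.0604), alveolar epithelial (0 of 12, 0.449) and ribosomal protein genes (1 of 16, 0.601). The donor-level permutation test called 17 lists. When all probes set the scaling 957 genes were higher and 66 lower, and in the authors' log2 values 151 genes were called, 53.0% of them higher.

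**Figure D4:**
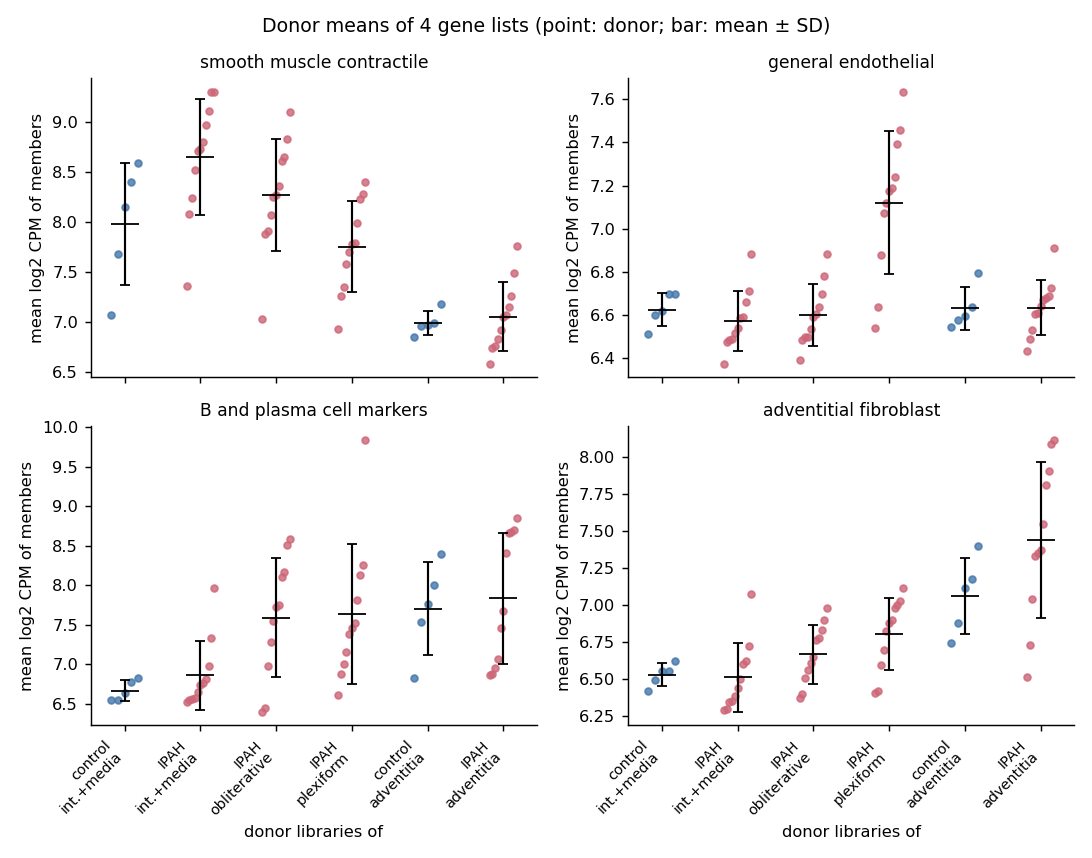
Donor means (log2 CPM) of the smooth muscle, general endothelial, B and plasma cell and adventitial fibroblast lists in the 6 groups of regions, 1 point per donor and group with the mean ± SD. The smooth muscle mean of intima and media is 8.65 ± 0.58 in IPAH and 7.98 ± 0.61 in control.

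IPAH intima and media were compared with control intima and media. No gene passed the test. The mean change in IPAH was 0.63 over 15 genes of the smooth muscle contractile list and -0.16 over 15 of the macrophage list. MYH11 was at 1352 ± 621 CPM in IPAH against 548 ± 337 (log2 1.102 ± 0.59, adjusted p = 0.624) and ACTA2 at 0.94 ± 0.67 (0.711), both named after their values were seen. By edgeR 0 of 8266 genes were called, against 684 at an unadjusted p under 0.05, and DESeq2 called 9. The 3 genes with the smallest p were LYZ (-0.50 ± 0.09, adjusted p = 0.0783), the olfactory receptor OR6C65 (-0.64 ± 0.13) and RGS5 (1.58 ± 0.32), which stood at 184 ± 89.5 CPM against 73.6 ± 22.7. Within plate 2 their changes were -0.49, -0.62 and 1.73, and for OR6C65 1 control donor lay far from the others. Camera called 5 lists, with smooth muscle higher (adjusted p = 1.46e-06; 1 gene over the list alone) and macrophage lower (0.000287; 2 genes over the list alone). It also called ribosomal protein higher (0.00138), complement lower (0.01; 1 gene over the list alone) and elastic fibre higher (0.0281). Only the macrophage call held with an estimated correlation (adjusted p = 0.0252). The others came to adjusted p = 0.723 with an estimated correlation. The complement call also ended without plate covariates (adjusted p = 0.548) and the elastic fibre call within plate 2 (0.0817). The pericyte list, not called by camera with plate covariates, was called higher without them (adjusted p = 0.0032) and within plate 2 (0.00104). In the donor-level test, which has no plate term, the macrophage mean differed by -0.10 (exact permutation p = 0.0011, adjusted 0.0366, within plate 2 -0.15 with exact permutation p = 0.0536). The smooth muscle mean differed by 0.67 (exact permutation p = 0.054, adjusted 0.287, within plate 2 0.71 with exact permutation p = 0.179), and by 0.32 in the fit without control donor 5. Within plate 2 the elastic fibre, ribosomal protein and complement means differed by 0.21, 0.48 and -0.12.

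Obliterative lesions were compared with control intima and media. DDIT4, a stress-induced inhibitor of mTOR signalling, was the one gene called higher and none was called lower. It stood at 130.09 ± 63.4 CPM against 89 ± 9 (log2 1.04 ± 0.18, adjusted p = 0.0216). Its change was 1.22 within plate 2 (adjusted p = 0.0034) and 0.58 without the plate terms, where the call was lost (adjusted p = 0.53). At an unadjusted p under 0.05 edgeR gave 683 genes, and DESeq2 called 1. Camera called 4 lists, none with an estimated correlation. They were ribosomal protein higher (2.29e-12, mean 0.72, adjusted p = 0.597 with an estimated correlation), smooth muscle higher (0.0128, mean 0.35, 0.848), macrophage lower (0.0128, 0.459) and neutrophil lower (0.0128, 0.459). Over the list alone 2 macrophage and 2 neutrophil genes passed, all lower. Without plate covariates the macrophage and neutrophil calls ended (adjusted p = 0.704 and 0.0566). The B and plasma cell list, at 0.0879 with them, was then called higher (7.28e-05), as it was within plate 2 (0.00281). The DDIT4 call was lost without control donor 1, 2, 4 or 5, and the donor-level test called 0 lists. Within plate 2 the ribosomal protein, smooth muscle, macrophage and neutrophil means differed by 0.87, 0.39, -0.19 and -0.31.

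Plexiform lesions were compared with control intima and media as well. No gene passed the test. PECAM1 was at 319.7 ± 139.9 CPM against 139.7 ± 18.2 (log2 1.19 ± 0.41, adjusted p = 0.364; within plate 2 1.29, adjusted p = 0.0399), CLDN5 at 1.41 ± 0.43 and SFTPC at 3.31 ± 0.98. These 3 were named after their values were seen. By edgeR 0 genes were called, against 1042 at an unadjusted p under 0.05, while DESeq2 called 32 and plate 2 alone 70, 67 of them higher. The smallest p belonged to FAM221B (-0.60 ± 0.11, adjusted p = 0.235), DDIT4 (1.59 ± 0.33, 1.81 within plate 2) and SSPN, sarcospan (-0.50 ± 0.11), for which 1 control donor lay far from the others. Within plate 2 the changes of FAM221B, SSPN, CLDN5 and SFTPC were -0.62, -0.45, 1.64 and 3.19. Camera called 12 lists higher: ribosomal protein (adjusted p = 3.89e-08), general endothelial (7.27e-07, 9 of 15 over the list alone), alveolar epithelial (0.000289, 6 of 12), fibrillar collagen (0.000289), red blood cell (0.000289, 3 of 3). Further ones were angiogenic sprouting (0.000944, 2 of 12), mesenchymal transition (0.00153, 2 of 8) and hypoxia (0.00292) genes, and pericyte (0.00514, 2 of 5), TGF-beta responsive (0.00606), pulmonary hypertension risk (0.00606, 4 of 11) and arterial endothelial (0.013). None held with an estimated correlation, at adjusted p = 0.358 to 0.52 with an estimated correlation. The donor-level test, which has no plate term, called 13 lists, with the general endothelial mean at 7.08 ± 0.33 (SD, n = 11) against 6.57 ± 0.07 (SD, n = 5). The difference was 0.50 (exact permutation p = 0.0082, adjusted 0.033), and 0.64 within plate 2 (exact permutation p = 0.0179, the smallest that 8 donors allow). Each of the other 11 lists also had a higher mean in IPAH within plate 2, from 0.27 for arterial endothelial to 0.99 for red blood cell genes.

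IPAH adventitia was compared with control adventitia. No gene passed the test. The mean change of the macrophage list was -0.28 over 15 genes, with CD163 at 116 ± 26.4 CPM against 183 ± 57.4 (log2 -0.96 ± 0.24), and that of the red blood cell list 0.48 over 3. The edgeR test called 0 genes, against 308 at an unadjusted p under 0.05, and DESeq2 called 0. CD163, APOD, an apolipoprotein (-1.30 ± 0.34), and CHMP6 (-0.41 ± 0.11) had the smallest p, each with adjusted p = 1.0, and stood at -0.98, -1.26 and -0.43 within plate 2. Camera called the macrophage list lower (adjusted p = 6.04e-05, 1 gene over the list alone), red blood cell genes higher (0.000848, 2 of 3) and complement lower (0.0355). None held with an estimated correlation (adjusted p = 0.378, 0.378 and 0.848, each with an estimated correlation). The macrophage call also ended without plate covariates (adjusted p = 0.0565). Within plate 2 the macrophage, red blood cell and complement means differed by -0.31, 0.47 and -0.34, and over all donors the complement mean turned in the donor-level test, at 0.0943.

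The difference of the disease effect between the layers was tested by an interaction with the donor as a block. No gene passed the test. The contrast of adventitia to intima and media differed in IPAH by a mean of -0.61 over 15 smooth muscle genes and of 0.38 over 13 adventitial fibroblast genes. The test called 0 genes by edgeR, against 477 at an unadjusted p under 0.05, and DESeq2 called 0. CCDC80 (0.85 ± 0.19, adjusted p = 0.634), IER3, an immediate early gene (0.60 ± 0.14), and SFRP2 (1.41 ± 0.36) had the smallest p. MYH11, named after its values were seen, stood at -1.02 ± 0.45 (0.847). Camera called smooth muscle (1.22e-11, 3 genes over the list alone), adventitial fibroblast (6.16e-07, 3 genes) and pericyte (0.0104, 1 gene), and each came to adjusted p = 0.356 with an estimated correlation. The exact permutation of donors gave p = 0.054, 0.088 and 0.064 for the smooth muscle, adventitial fibroblast and pericyte means, adjusted 0.602. In none of the 10 comparisons did camera call the proliferation, airway epithelial, proteoglycan, capillary endothelial, or venous and systemic endothelial lists, although single members passed, such as OGN, a small matrix proteoglycan, in plexiform lesions against intima and media (-0.58 ± 0.08). Only 5 proliferation genes were measured, with group means of 6.59 (plexiform lesions) to 6.69 log2 CPM (control adventitia), and 9 each of the capillary and the venous and systemic lists. The lack of a call there does not show a lack of change.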

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

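Among the tests of explanations, those of plate for the smooth muscle list, of background compression and of the share of background counts were chosen after the result was seen, as were the donor-level permutation and the scaling by all probes.

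The smooth muscle list was higher in IPAH than in control intima and media, with a mean shift of 0.67 ± 0.46 (SE) over donors. Within plate 2 the shift was 0.71 ± 0.45, as large as over all donors, but 0 lies within 2 SE (exact permutation p = 0.179), so plate is not excluded. A single control donor could account for much of it: without control donor 5 the shift was 0.32 ± 0.44, the lowest of the 5 values with 1 control donor left out. That donor's summed library is led by 1 very deep region of 11963856 counts, beside 390534 to 1803846 in its other regions. In the deep region the median named gene lay at only 1.104 times the median unnamed probe. Whether the donor or this region lowers the list was not tested. More adventitia in the control regions would bring a shift of -0.37 in the adventitial fibroblast list, whose shift was -0.0754 ± 0.0857. That falls short of the full amount, but a smaller part of it lies within 2 SE, so such a mixture and disease cannot be told apart. Capture also differed between the groups. The 7 regions segmented by smooth muscle actin all came from a single IPAH donor, whose intima and media were actin-positive segments. The shift of the list without them was not tested. Any other choice of regions that differed between the groups was not tested either and stays open too.

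The contrast of adventitia to intima and media was more negative in IPAH for the smooth muscle list (-0.61) and the pericyte list (-0.30), and more positive for the adventitial fibroblast list (0.38). The camera test of the difference itself called these 3 at the preset correlation and none with an estimated one (adjusted p = 0.356 each). Compression of fold changes by background in the control libraries was looked at by the slope of the control contrast on the IPAH contrast. It was 1.04 over 51 genes of 4 other lists (bootstrap interval 0.887 to 1.17) and 0.636 for smooth muscle. The interval was taken over genes and does not cover the spread between control donors. The 51 genes also include immunoglobulin genes with large changes, which may lead the slope. The slopes therefore cannot decide whether the smooth muscle contrast was compressed, and this stays open. Plate 1, which holds IPAH regions only, is argued against by plates 2 and 4 alone, where the difference was -0.78 ± 0.35 against -0.61 ± 0.30 with all plates. The exact permutation of donors gave p = 0.054, so chance stays open. In a single IPAH donor, and in no control donor, adventitia was captured as actin-negative and intima and media as actin-positive segments. This bears on the smooth muscle contrast, and the list difference without that donor was not tested. Any other choice of regions that differed between the groups was not tested and may stay open too.

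In plexiform lesions 1325 genes were lower than in IPAH intima and media. Whether most of these falls reflect a smaller share of background counts in the lesions cannot be told. The files also do not state whether the unnamed probes stand for background. With all probes setting the scaling 212 falls were left, while 1355 of the 1356 rises passed. A change of scaling shifts all genes of a library alike, and the falls were small, at a median of -0.19 against 0.31 for the rises. An upward shift therefore ends small falls whatever their cause. The genes that fell lay at 1.28 times the median unnamed probe and those that rose at 1.73 times. The median named gene over all regions lay at 1.25 times, so the falls lay near the usual level and the rises above it. Of the smooth muscle genes 15 of 15 were still lower with all probes in the scaling, with a median of -0.78, so the change of scaling was too small to end their falls. If the unnamed probes stand for background, this argues against a smaller background share for these genes.

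Of 91 gene levels tested in the groups of 5 control donors, 7 had 1 donor far from the other 4, against 4.55 by chance. The gap to the nearest donor as a share of the range was 0.809 for CCL21, 0.813 for IGFBP3, 0.776 for OR6C65 and 0.802 for SSPN in control intima and media, and 0.750 for C11orf96, 0.719 for LMOD1 and 0.799 for SLC34A2 in control adventitia. Probes without a gene name, which entered no comparison, also differed within the IPAH lungs: 33 in obliterative lesions against intima and media, 1181 in plexiform lesions against intima and media, 135 in plexiform against obliterative lesions and 155 in adventitia against intima and media. In the 2 regions labelled as lymph in IPAH, both from 1 donor, the lower of the pair had a T and NK cell list mean of 6.81 log2 CPM, above the highest of 67 control regions (6.74) but below the highest of 150 other IPAH regions (7.00). Its ribosomal protein mean was 9.48, above the control highest of 9.30 and below 10.03 in the other IPAH regions.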

How the results depend on the processing

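The scaling by all probes, the authors' log2 values, the background filter, the regions without those over 10 times the median total and the donor-level list test were chosen after seeing the data. The gene counts of the 10 comparisons and the numbers of lists called moved by over 1.5 times as follows; the cause was not tested unless given.

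With DESeq2, 9 genes were called for IPAH against control intima and media and 32 for plexiform lesions against control, where edgeR called 0. Upper-quartile factors gave 2 for IPAH against control intima and media and 0 for obliterative lesions against control, and leaving out the regions segmented by smooth muscle actin gave 2 for the first. Without plate covariates obliterative lesions against control gave 0 and plexiform lesions 16. Plate 2 alone gave 1 for intima and media, 11 for obliterative and 70 for plexiform lesions. Plate 4 alone gave 3 for obliterative lesions, 2 for plexiform lesions and 6 for adventitia, with its lone control assumed to vary like the IPAH donors. With plate as a fixed term and the donor as a random block (voom, limma) the counts were 1 for intima and media, 23 for obliterative lesions, 277 for plexiform lesions and 24 for adventitia against control.

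Means of the regions with limma-trend gave 0 for obliterative lesions against control, 159 for obliterative and 1427 for plexiform lesions against IPAH intima and media, 281 for plexiform against obliterative lesions and 214 for control adventitia. With no donor block in place of the donor block the last 4 comparisons gave 0, 588, 65 and 16, and IPAH adventitia 310. With donor and plate together as the block control adventitia gave 134. With 1 control donor left out, IPAH against control intima and media gave 0 to 2 genes (2 without control donor 4), obliterative lesions against control 0 to 1 (0 without control donor 1, 2, 4 or 5), plexiform lesions 0 to 0, adventitia 0 to 0, the interaction 0 to 0, and control adventitia 3 to 196 (104, 58, 9, 3 and 196 without donors 1 to 5). Leaving out 6 regions over 10 times the median total gave 0 for obliterative lesions against control and 205 for control adventitia.

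In the authors' log2 values with limma the counts were 0 for obliterative lesions against control, 1 for obliterative lesions, 462 for plexiform lesions and 332 for adventitia against IPAH intima and media, and 151 for plexiform against obliterative lesions. With all probes in the scaling control adventitia gave 33 of 86; the share of rises went from 50.6% to 92.2% for plexiform and from 72.7% to 90.6% for obliterative lesions against IPAH intima and media, from 71.0% to 93.5% for plexiform against obliterative lesions, and the median change of all genes went from -0.0133 to 0.114 for plexiform lesions against control and from -0.0188 to 0.0837 against IPAH intima and media. The background filter, at 2 times the median unnamed probe, tests 447 to 826 genes. It gave 2 for intima and media, 0 for obliterative lesions and 1 for adventitia against control, 180 for obliterative lesions, 343 for plexiform lesions and 190 for adventitia against IPAH intima and media, 180 for plexiform against obliterative lesions and 1 for the interaction. Within IPAH and control lungs it turned the balance of rises and falls to 80 and 100 for obliterative lesions, 84 and 106 for IPAH adventitia and 35 and 50 for control adventitia, each against intima and media, and gave 171 and 172 for plexiform lesions.

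With the correlation estimated, lists called were 1, 0, 0 and 0 against control (intima and media, obliterative lesions, plexiform lesions, adventitia), 2 for obliterative lesions, 0 for plexiform lesions and 5 for adventitia against IPAH intima and media, 5 for plexiform against obliterative lesions, 0 in control adventitia and 0 for the interaction. The donor-level permutation called 1 list for intima and media, 0 for obliterative lesions, 0 for adventitia against control and 0 for the interaction. Without plate covariates 9, 20 and 5 lists were called for obliterative lesions, plexiform lesions and adventitia against control. The complement list in IPAH against control adventitia turned without plate covariates (adjusted p = 0.552) and in the donor-level permutation (adjusted p = 0.995).

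Of the values of named genes under the alternatives, 4077 kept direction and side of the threshold, 797 lost the call, 25 gained it and 25 turned. In the authors' log2 values the turned ones were, for obliterative lesions against IPAH intima and media, IGLL5 -0.19, SFTPC -0.16, C1QB -0.0243, LYZ -0.17, JCHAIN -0.12, SFTPB -0.0921, SFTPA2 -0.33 and NAPSA -0.0809; for plexiform lesions RGCC -0.0704, CCL21 -0.0156, TGFB3 0.0027, TRBC1 -0.0634, CD5 0.0093, IGHA1 -0.37 and SFTPA2 -0.0640; for plexiform against obliterative lesions SPP1 -0.0130; for IPAH adventitia TRBC1 -0.0398 and MZB1 -0.10; and for control adventitia SLC34A2 -0.0220. With the background filter LTBP4 (-0.11), ZEB2 (-0.0928), GATA2 (-0.0799) and RGS5 (-0.0297) turned in plexiform lesions against IPAH intima and media, and TAP1 turned there with region means (-0.0297) and with no donor block (-0.0384). DDIT4 in obliterative lesions against control ran from 0.24 to 1.22 over 17 alternatives, with adjusted p from 0.00105 to 0.998, and lost its call in 11. The planned filter by negative controls and the planned removal of regions under 0.1 of the median total were not run, since no probe is marked as a negative control and 0 regions lay below that limit; the planned run with no low-count filter moved nothing, since all 8266 genes pass the filter. Signal over the unnamed probes is low: 505 genes lay above 2 times their median.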

Other observations

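The genes of the major histocompatibility complex were looked at after the data were seen and belong to no fixed list, and the tests of other groupings of the donors were planned. Of 21 measured genes of antigen presentation, 15 rose in plexiform lesions against IPAH intima and media and 1, HLA-DQA2, fell by 0.18 on the log2 scale. B2M, the light chain of class I molecules, rose by 1.23 ± 0.13 (SE), from 136 ± 63.8 to 343 ± 197 CPM, with HLA-C at 1.37 ± 0.12, HLA-E at 1.44 ± 0.15, and the class II chains HLA-DRA at 1.17 ± 0.16 and HLA-DPA1 at 1.07 ± 0.14. The peptide transporter genes TAP1 and TAP2 were at 0.01 ± 0.05 and 0.01 ± 0.05 and did not pass. Their levels were low, at 84.1 and 81.8 CPM in the lesions. The median named gene lay at only 1.25 times the median unnamed probe, and whether these 2 genes were detected was not tested. A lack of change cannot be read from them. Of the 21 genes, 13 rose in obliterative lesions against IPAH intima and media, 13 in plexiform against obliterative lesions and 15 in IPAH adventitia against intima and media, and none fell there. In control adventitia, with 5 donors, edgeR called 0 of them. Their estimates pointed the same way there, and only HLA-DOB was below 0, at -0.07 ± 0.09. CD74 was at 1.34 ± 0.38 and HLA-B at 0.90 ± 0.47, each higher in 5 of 5 donors. The lack of calls therefore does not show that the rise is absent in control lungs. The difference from IPAH was not tested for this set.

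The 3 regions labelled as lymph, 2 in 1 IPAH lung and 1 in a control lung, entered no comparison. The lymphocyte genes named here were picked among those whose level in the IPAH ones lay furthest above the highest of 67 control regions, so that excess tests nothing. The B and plasma cell list, fixed before, had means of 7.62 and 8.14 log2 CPM in them. That is below the highest of the control regions (9.03) and of the other IPAH regions (10.30). CXCL13, a chemokine that attracts B cells, was at 8.53 and 9.09 log2 CPM in the IPAH regions and 6.94 in the control one, against a median of 6.34 and a highest value of 7.10 over the control regions. LTB, a cytokine of lymphoid tissue, was at 8.29 and 8.42 in IPAH and 6.59 in the control one, below the control median of 6.78 (highest 7.28). BANK1, a B cell adaptor, was at 8.31 and 8.35 against 7.61 (control median 6.85, highest 7.45), and the T cell receptor gene TRBC1 at up to 8.32 against 6.86 (control median 6.35, highest 7.15). A few genes took a large share of counts over all regions together, with PTBP1 at 6.46% of named counts and up to 17.3% in a region.

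Other groupings of the donors, 40 for each comparison but 16 for control adventitia with the real one included, tested whether chance gives as many calls. For genes only the real grouping, 1 of 40, gave as many in the 4 comparisons within the IPAH lungs. It gave 337 against at most 79 in the others for obliterative lesions against intima and media, and 2681 against 2057 for plexiform lesions. Plexiform against obliterative lesions gave 827 against 708, and adventitia 814 against 678. That share is the smallest that 40 groupings allow and was not adjusted over comparisons, so it argues against chance without excluding it. In control adventitia 1 of 16 gave as many genes (86, highest other 2) and 3 of 16 as many lists (12, highest other 15), and 16 groupings are too few for a share under 0.05. For obliterative lesions against control 5 of 40 gave at least the 1 gene called (highest other 7), so chance is not excluded. Where the real count is 0 the outcome is fixed at 40 of 40 and tests nothing. The highest other was then 5 for intima and media, 54 for plexiform lesions and 6 for adventitia against control, and 3 for the interaction. For lists chance is not excluded: as many were called in 21 of 40 groupings for intima and media (5, highest other 12), 27 for obliterative lesions (4, highest other 18), 8 for plexiform lesions (12, highest other 18) and 35 for adventitia against control (3, highest other 17), and in 26 for the interaction (3, highest other 16). Within IPAH the numbers were 2 for obliterative lesions (10, highest other 10), 2 for plexiform lesions (20, highest other 21), 3 for plexiform against obliterative lesions (18, highest other 19) and 6 for adventitia (11, highest other 13).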
